A study of Danio rerio with 16 samples.

How the data were processed

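Per the labels' protocols, total RNA of whole embryos was extracted with TRIzol and 1 µg went into libraries made with the VAHTS Universal V8 kit. The labels give 16 libraries in 4 groups of 4, sibling and hnf4a, hnf4b double knockout embryos at 34 and 48 hpf. The authors deposited raw counts per gene symbol. Per the submitters' processing notes, the tools were FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10b and featureCounts 2.0.6 with the genome build GRCz11. The strand setting, the treatment of reads with several alignments and the annotation are not given in the sources used here. Genes with near-identical copies, such as the apoa4b, c3a, her4, crystallin and carboxylesterase genes, and overlapping or antisense genes are therefore uncertain, since reads could be split between them or lost.

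The table held 36109 gene symbols, and 24084 were tested after edgeR's filterByExpr. Counts were scaled by TMM and all 16 libraries fitted in a single model of 4 groups, with edgeR 4.0.16 (glmQLFit, glmQLFTest) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Levels are given as CPM from the TMM-scaled library sizes, with the SD over 4 libraries, and log2 fold changes with their standard errors. The comparisons were knockout against sibling at each stage, the difference between these, and the siblings of 48 against those of 34 hpf. Where a group had 0 counts, a fold was set against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval. Intervals and floors cover counting error only.

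The groups, the tests, the 33 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Named genes were hnf4a, hnf4b and hnf4g and the 8 largest rises and falls of each knockout comparison among called genes with an average log2 CPM of at least 1, no overlap between the groups and a symbol without the clone, accession and locus prefixes set beforehand. The locus identifier XLOC_000695 begins with none of these and so stayed in. For the difference the 5 largest either way were named, for the stages the 6 largest without the overlap criterion. From each list and comparison the 4 members with the smallest p were eligible where at least 1 passed and otherwise 2, and every apolipoprotein was eligible. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation. The pattern of the ribosomal list also takes in S6 kinase genes, and a list without them was added after the data were seen.

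Within a stage, deviations of same-numbered sibling and knockout libraries from their group means, taken over 24084 genes, correlated at 0.155, 0.267, 0.279 and 0.208 at 34 hpf and at 0.284, 0.174, 0.191 and 0.430 at 48 hpf. All 8 lie above 0.1, so by the rule set beforehand the numbers were taken to pair the samples. Only 4 of the 8 were the highest among the numbers, so the pairing is uncertain. The pairing comes from these values and from the repeat number in the labels, which do not say what a number marks. No pair of libraries in a group agreed within counting noise (smallest mean ratio to it 8.29). The first principal component held 32.0% of the variance and parted the stages, and the next held 19.6% and parted the genotypes. The component after these (11.7%) parted replicates 1 and 2 from 3 and 4 at 34 hpf and 1 and 4 from 2 and 3 at 48 hpf, in both genotypes.

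Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors or upper quartile scaling in edgeR, a robust dispersion prior, no filter on low counts, a CPM of at least 1 in 4 libraries, a test against a fold change of 1.5, only the compared libraries, the replicate block, and each library left out in turn. On simulated counts with 200 changed genes, edgeR recovered 50.8% of the 2-fold and 74.2% of the 4-fold changes at 34 hpf (23724 genes), with 5 unchanged genes among 97 calls. The corresponding values were 50.8% and 81.8% at 48 hpf (23687 genes), 40.3% and 68.2% for the difference (23721 genes) and 55.2% and 81.8% for the stages (23709 genes). Unchanged genes made up 3 of 111 calls at 48 hpf, 7 of 79 for the difference and 3 of 111 for the stages. Of 1.5-fold changes 13.4%, 29.9%, 0% and 25.4% were recovered. Python tables used numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.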

Results

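Whole zebrafish embryos lacking both hnf4a and hnf4b were compared with their siblings at 34 and 48 hours post-fertilisation (hpf) by RNA sequencing. Hnf4 proteins are nuclear receptors of the liver, gut and yolk syncytial layer, the tissue that packages yolk lipid into lipoproteins. The 16 libraries fell into 4 groups of 4. At 34 hpf the total counts were 35586032 to 42407778 in siblings and 34588058 to 41000857 in knockouts. At 48 hpf they were 36186542 to 38101069 and 40677285 to 43194625. The title of the series names yolk lipid mobilisation and growth after segmentation as its subject. The labels do not say that replicates came from separate clutches, so the p-values measure the spread between these samples.

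Transcripts of the targeted genes did not separate the genotypes. At 34 hpf hnf4a stood at 12.8 ± 1.92 CPM in siblings and 12.1 ± 4.77 CPM in knockouts (mean ± SD, n = 4), a log2 fold change of -0.08 ± 0.27 (SE) with adjusted p = 0.897 in edgeR's quasi-likelihood test. At 48 hpf its log2 fold change was -0.15 ± 0.27 (adjusted p = 0.789). For hnf4b the values were -0.91 ± 0.48 (adjusted p = 0.269) at 34 hpf and -0.83 ± 0.48 (adjusted p = 0.329) at 48 hpf. Without sibling 34 hpf replicate 1 the first of these was -0.29. The paralog hnf4g was at 0.42 ± 0.46 (adjusted p = 0.649) and 0.35 ± 0.44 (adjusted p = 0.697). An allele that leaves its transcript in place would give such levels, so they do not check the genotype labels.

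The first comparison asked what the double knockout changed at 34 hpf. Apolipoprotein transcripts took 1.88 ± 0.205% of all counts in siblings and 0.390 ± 0.200% in knockouts (n = 4). Of 17 apolipoproteins tested, 13 fell, 0 rose and 4 were not called. The structural proteins of lipoprotein particles apobb.1 and apoba fell from 8616 to 1433 CPM (log2 fold change -2.59 ± 0.37) and from 1217 to 237 CPM (-2.36 ± 0.31). The gene apoa1b, of high-density lipoprotein, changed by -4.34 ± 0.70. The apolipoprotein E gene apoea fell from 219 ± 154 to 0.50 ± 0.54 CPM (-8.79 ± 0.67, adjusted p = 4.34e-07). The fall of apoc1 (-1.06 ± 0.32, adjusted p = 0.0471) was lost in 6 of 8 omissions of a single library, those of each sibling library and of knockout replicates 1 and 3 (highest adjusted p = 0.141), and with a robust dispersion prior (adjusted p = 0.0843).

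Members of the lists for lipoprotein assembly, liver, blood plasma and gut fell with them at 34 hpf. Whole embryos do not show in which tissue they fell, and the lists share some members. In the list of lipoprotein assembly and secretion 9 of 19 members fell and 0 rose, among them the microsomal triglyceride transfer protein gene mttp (-3.02 ± 0.21), the triglyceride synthesis gene dgat2 (-3.65 ± 0.59) and soat1 (-1.77 ± 0.30). In coagulation and complement 21 of 24 fell and 0 rose, with c8b at -7.01 ± 0.34, f9b at -5.79 ± 0.43, f7 at -6.74 ± 0.85 and serpind1 at -4.11 ± 0.34. Among hepatocyte genes 11 of 19 fell and 1 rose. The fibrinogen genes fga and fgb changed by -2.95 ± 0.34 and -6.32 ± 0.90 and ambp by -3.06 ± 0.36. In the yolk syncytial layer list 6 of 11 fell and 1 rose, the protease gene lgmn (0.89 ± 0.10). In the intestinal list 6 of 18 fell and 1 rose, with the lipid binding protein gene fabp2 at -4.64 ± 0.24 and the retinol binding protein gene rbp2a at -4.11 ± 0.60. Among the apolipoproteins 14 fell and 1 rose when adjusted over the list alone. The lower and higher members of the other lists in this order were 11 and 0, 22 and 0, 13 and 1, 7 and 1, and 6 and 1.

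Camera called these lists lower, and with an estimated correlation the yolk syncytial layer list lost its call (adjusted p = 0.0552 with an estimated correlation). The apolipoprotein list kept it (adjusted p = 0.0419 with an estimated correlation). Without knockout replicate 4, which held the highest apolipoprotein share of the knockouts (0.659%), the fitted falls were larger for apoea (-9.82), apoa1b (-5.79), dgat2 (-4.44), fgb (-11.01) and rbp2a (-5.28). All knockout counts of f7 came from replicate 2, so without it only a lower bound of the fall is left.

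Part of the genes of sterol and fatty acid synthesis rose at 34 hpf. Of 26 cholesterol synthesis genes and targets of the sterol regulator SREBP2, 14 rose and 0 fell, among them insig1 (1.89 ± 0.19), cyp51 (1.88 ± 0.23) and srebf2 itself (0.98 ± 0.13). In fatty acid synthesis 5 of 15 rose and 2 fell, with the desaturase genes scd (2.79 ± 0.29) and fads2 (2.26 ± 0.24) and srebf1 (1.26 ± 0.13) higher and the elongase gene elovl5 (-3.14 ± 0.29) lower. Among lipoprotein receptors and lipases 4 of 17 rose and 2 fell, with the lipid transfer protein gene pltp at 2.32 ± 0.22 and the lipase gene lipg at 1.18 ± 0.13. In these lists 19, 5 and 7 members rose and 2, 3 and 3 fell when adjusted over the list alone. Camera called the 3 lists higher, and none kept its call (adjusted p = 0.0824, 0.264 and 0.160 with an estimated correlation).

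Stress, tissue and energy genes moved in part at 34 hpf. Of 16 genes of the p53 response 6 rose and 0 fell, such as bbc3 (1.03 ± 0.19) and sesn1 (1.01 ± 0.20), and camera called the list higher (adjusted p = 0.160 with an estimated correlation). In the unfolded protein response 4 of 23 fell and 1 rose, with manf at -0.74 ± 0.15 and dnajb11 at -0.70 ± 0.14 (adjusted p = 0.165 with an estimated correlation). Of 12 mitochondrially encoded genes 10 fell, mt-nd2 by 0.92 on the log2 scale, while the mitochondrial share of counts was 3.30 ± 0.312% in siblings and 2.38 ± 0.273% in knockouts. Among epidermal genes 4 of 20 rose, such as krt8 (0.73 ± 0.11) and the calcium channel gene trpv6 (1.04 ± 0.20), with adjusted p = 0.0601 with an estimated correlation. The ribosomal list was called higher with 3 of 95 members higher and 1 lower (adjusted p = 0.603 with an estimated correlation). The lens crystallin list was called lower with 0 of 20 members called (adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, the members higher and lower in these lists were 6 and 0, 1 and 15, 0 and 11, 5 and 1, 3 and 1, and 0 and 0.

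Other lists did not pass camera at 34 hpf, although they held single calls. The stress response list had 7 higher and 4 lower of 23, with the transcription factor gene ddit3 at 1.34 ± 0.12 and the asparagine synthetase gene asns at -0.85 ± 0.14. The growth factor axis had 2 higher and 3 lower of 22, with igfbp1b, a binding protein of insulin-like growth factors, at 4.02 ± 0.54 and igfbp2a at -1.50 ± 0.16. Its relative igfbp1a rose by 0.98 ± 0.25 (adjusted p = 0.0214), and the call was lost without sibling replicates 1 or 4 or knockout replicates 1 or 3 (highest adjusted p = 0.0636). In the amino acid and glucose list 2 rose and 3 fell of 24 (pck2 -0.91 ± 0.11; fbp1b -3.47 ± 0.65, or -5.21 without knockout replicate 4). In fatty acid oxidation 1 rose and 3 fell of 31 (pdk2b 2.16 ± 0.25), and in hypoxia and glycolysis 1 rose and 3 fell of 24 (ldha -0.70 ± 0.09). The iron, copper and retinoid list had 1 higher and 3 lower of 16 (fth1b 1.21 ± 0.14) and pronephros 0 and 3 of 20 (cdh17 -0.88 ± 0.08). The counts were for muscle 0 and 5 of 26 (acta1b -0.74 ± 0.12), neurons and retina 0 and 3 of 20 (atoh7 -1.68 ± 0.21; otx5 -1.07 ± 0.21, adjusted p = 0.0525 in limma-voom). They were for lysosome 2 and 0 of 23, endothelium 3 and 0 of 21 (egfl7 0.60 ± 0.13), leukocytes 1 and 0 of 19 (irg1l 2.31 ± 0.50) and replication 0 and 1 of 25. None was called of 7 exocrine and 12 endocrine pancreas, 23 erythroid, 10 hatching gland and 18 cartilage genes. The higher and lower members adjusted over the list alone were 7 and 5 (stress), 5 and 4 (growth factors), 2 and 4 (amino acids), 1 and 4 (oxidation), 1 and 3 (hypoxia), and 1 and 7 (iron). For the rest they were 2 and 3 (pronephros), 0 and 5 (muscle), 0 and 3 (neurons), 3 and 0 (lysosome), 3 and 0 (endothelium), 1 and 0 (leukocytes), 1 and 2 (replication) and 0 in the last 5. With the replicate block camera called erythroid (adjusted p = 0.0349), neurons and retina (0.0371), iron (0.00530) and hypoxia (0.0426) lower and hatching gland higher (0.0162). Without the block none passed (in this order adjusted p = 0.810, 0.699, 0.603, 0.597 and 0.306 with an estimated correlation). Medians or means differed in sign from the test for pronephros (median 0.01, test lower), leukocytes (mean -0.10, test higher) and cartilage (mean -0.28, test higher).

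Over all 24084 genes tested, 985 were higher and 1255 lower at 34 hpf, and 178 and 398 of these differed by more than 2-fold. The largest falls were those of itih3a and habp2, plasma protein genes with 0 counts in the knockouts, which were at least 794-fold and at least 266-fold lower (floor of 3 counts over the group). After these came c3a.3 (-8.85 ± 1.42), apoea, spam1 (-7.96 ± 0.52), c8b, f7 and akr1a1a (-6.46 ± 0.60). The largest rises were hpxa, the locus XLOC_000695 (4.31 ± 0.75), igfbp1b, klf10 (3.05 ± 0.71), scd, arf4b (2.76 ± 0.64), cyp24a1 and gtf3ab (2.51 ± 0.54). The rise of hpxa, a hemopexin gene (4.31 ± 1.16, adjusted p = 0.0264), rested on knockout replicate 2, without which it was 1.72 (adjusted p = 0.235). The call was also lost without any 1 of the 4 sibling libraries. That of cyp24a1, a vitamin D hydroxylase gene (2.68 ± 0.65), was lost without knockout replicate 1 (1.89, adjusted p = 0.0566). Without knockout replicate 3 XLOC_000695 was at 3.46 and c3a.3 at -10.26, without replicate 2 gtf3ab was at 1.81. Without replicate 4 spam1 was at -9.02 and akr1a1a at -8.79. In limma-voom the calls of c3a.3 (adjusted p = 0.513), hpxa (0.477), arf4b (0.410), gtf3ab (0.0897) and cyp24a1 (0.0711) were lost. Those of hpxa (0.0543) and gtf3ab (0.0538) were also lost with only the compared libraries, and that of hpxa with a robust dispersion prior (0.0708). The number of higher genes was 646, 522 and 584 without sibling replicate 1, sibling replicate 2 or knockout replicate 3, and that of lower genes 1982 without knockout replicate 4. Higher genes made up 44.0% of the calls, and 1375 higher and 1078 lower genes (56.1% higher) were called with upper quartile scaling.

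**Figure D1:**
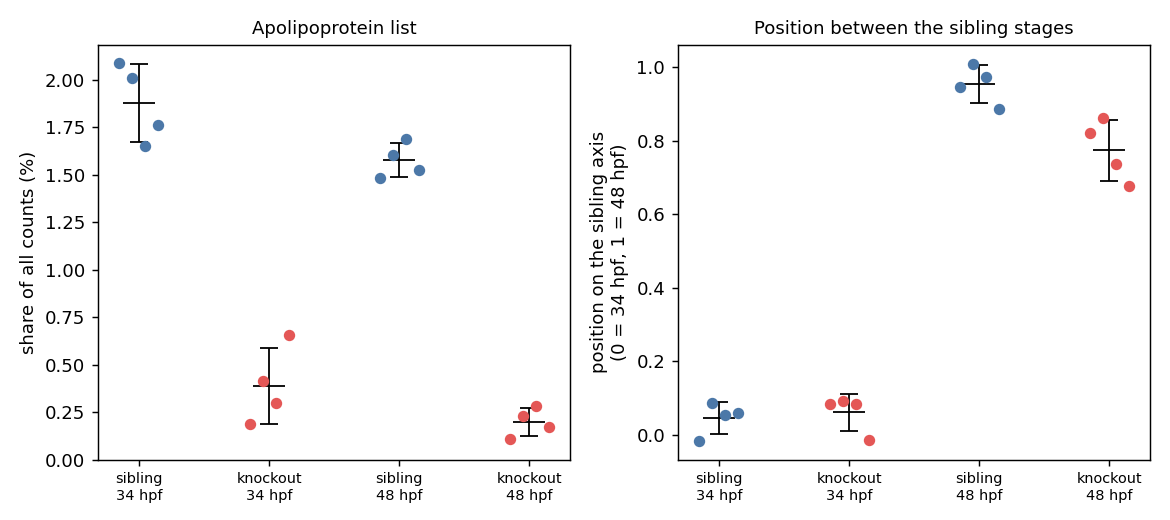
Share of all counts taken by the apolipoprotein list (left, %) and position between the mean sibling profiles of 34 hpf (0) and 48 hpf (1) on the right, for each of the 16 libraries, with the group mean and SD as lines. All 8 knockout libraries lie at or below 0.659% and all 8 sibling libraries at or above 1.49% on the left.

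The second comparison asked the same at 48 hpf. Apolipoproteins took 1.58 ± 0.0901% of counts in siblings and 0.199 ± 0.0745% in knockouts (n = 4), and 13 of 17 fell with 0 higher. The genes apobb.1 and apoba changed by -3.57 ± 0.38 and -2.05 ± 0.30, apoa1b fell from 2263 ± 221 to 16.5 ± 7.89 CPM (-7.10 ± 0.80). The genes apoa4b.1 (-11.21 ± 1.95), apoea (-10.29 ± 0.73) and the lipase cofactor gene apoc2 (-9.11 ± 1.35) were among the largest falls. In lipoprotein assembly 9 of 19 fell and 0 rose, with mttp at -2.23 ± 0.21, dgat2 at -4.07 ± 0.61 and pla2g12b at -3.85 ± 0.62. In coagulation and complement 21 of 24 fell and 0 rose (c8b -5.85 ± 0.31; f9b -5.06 ± 0.40). Among hepatocyte genes 14 of 19 fell and 1 rose, with fga at -3.90 ± 0.35, ambp at -3.33 ± 0.36 and the transferrin gene tfa at -3.12 ± 0.44, or -3.77 without knockout replicate 2. In the yolk syncytial layer list 6 of 11 fell and 1 rose. In the intestinal list 5 of 18 fell and 0 rose (fabp2 -4.72 ± 0.24; rbp2a -5.69 ± 0.66, or -6.42 without knockout replicate 2). The lower and higher members adjusted over the list alone were 13 and 0, 12 and 1, 22 and 0, 15 and 1, 7 and 2, and 5 and 2. All 6 lists were lower by camera, with adjusted p of at most 0.0411 with an estimated correlation.

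Most of the sterol genes and part of the fatty acid and stress genes rose at 48 hpf. Of 26 cholesterol genes 21 rose and 0 fell, including cyp51 (2.79 ± 0.24), msmo1 (2.67 ± 0.32) and insig1 (1.84 ± 0.19). In fatty acid synthesis 7 of 15 rose and 3 fell (fads2 2.87 ± 0.24; srebf1 1.71 ± 0.13; elovl5 -2.69 ± 0.29). Among lipoprotein receptors and lipases 7 of 17 rose and 3 fell (pltp 2.84 ± 0.23; the lipase gene lpl 0.75 ± 0.11). In the stress response list 9 of 23 rose and 2 fell, with ddit3 at 23.8 ± 2.67 CPM in siblings and 91.5 ± 12.3 CPM in knockouts (1.94 ± 0.12) and atf5a at 0.82 ± 0.13. In the hatching gland list 5 of 10 rose, with the hatching enzyme gene he1.1 at 1.57 ± 0.30 and the protease gene ctslb at 2.20 ± 0.45, or 1.26 without knockout replicate 1. Among epidermal genes 5 of 20 rose and 0 fell (krt8 0.86 ± 0.11). Adjusted over the list alone, 24, 7, 9, 12, 6 and 6 rose and 0, 3, 3, 3, 0 and 0 fell. All 6 lists were higher by camera, with adjusted p of at most 0.0410 with an estimated correlation.

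Further lists passed camera at 48 hpf only with its preset correlation, apart from the mitochondrial one. Of 12 mitochondrially encoded genes 8 fell (mt-nd2 -0.60 ± 0.11), and camera gave adjusted p = 0.0411 with an estimated correlation. All symbols with the prefix mt- together took 3.46 ± 0.101% of counts in siblings and 2.73 ± 0.314% in knockouts. The list of neurons and retina was lower with 8 of 20 lower and 1 higher (vsx1 -1.37 ± 0.17; the photoreceptor factor gene crx -1.47 ± 0.25; adjusted p = 0.106 with an estimated correlation). The unfolded protein response was lower with 8 of 23 lower and 1 higher (dnajb11 -0.65 ± 0.14; hsp90b1 -0.61 ± 0.13; adjusted p = 0.201 with an estimated correlation). Cartilage was lower with 4 of 18 lower (acana -0.93 ± 0.17; matn1 -3.83 ± 0.80, or -5.31 without knockout replicate 2; adjusted p = 0.221 with an estimated correlation) and muscle with 3 of 26 lower (acta1b -1.14 ± 0.12; adjusted p = 0.237 with an estimated correlation). Hypoxia and glycolysis had 6 of 24 lower and 1 higher (ldha -0.87 ± 0.09; adjusted p = 0.237 with an estimated correlation) and iron 5 of 16 lower and 1 higher (fth1b 1.09 ± 0.14; adjusted p = 0.247 with an estimated correlation). Fatty acid oxidation had 6 of 31 lower and 1 higher (pdk2b 2.13 ± 0.24; adjusted p = 0.362 with an estimated correlation) and lens 0 of 20 called (adjusted p = 0.472 with an estimated correlation). Adjusted over the list alone, the lower and higher members in this order were 10 and 0, 11 and 1, 14 and 3, 5 and 0, 9 and 0, 7 and 1, 5 and 1, 6 and 1, and 0 and 0.

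Higher lists were the ribosomal proteins with 25 of 95 higher (rps12 0.44 ± 0.08; rpl4 0.33 ± 0.07; adjusted p = 0.237 with an estimated correlation) and the p53 response with 5 of 16 (bbc3 1.04 ± 0.19; adjusted p = 0.106 with an estimated correlation). The lysosome list was higher with 6 of 23 (ctsba 1.31 ± 0.27; adjusted p = 0.201 with an estimated correlation) and endothelium with 5 of 21 higher and 1 lower (cxcr4a 0.79 ± 0.16; prox1a -0.54 ± 0.09; adjusted p = 0.247 with an estimated correlation). The growth factor axis was higher with 6 of 22 higher and 1 lower (igfbp1b 4.92 ± 0.56; igfbp1a 1.84 ± 0.26; irs2a 1.01 ± 0.16; adjusted p = 0.201 with an estimated correlation) and leukocytes with 3 of 19 (adjusted p = 0.329 with an estimated correlation). The 3 leukocyte calls, il1b, mmp9 and mmp13a, rested on knockout replicate 1. The cytokine gene il1b stood at 23.5 CPM there and at most 0.359 CPM in the other knockouts. Without that library its log2 fold change was 0.87 (adjusted p = 0.650), that of mmp9 0.54 (adjusted p = 0.316) and that of mmp13a 0.91 (adjusted p = 0.0515). With the replicate block their adjusted p were 0.109, 0.109 and 0.0526. The gene il1b also lost its call without sibling replicates 1, 2 or 4, and mmp9 without any 1 of the 4 sibling libraries. All 3 lost their calls in limma-voom (adjusted p = 0.386, 0.189 and 0.161), and il1b and mmp9 also with only the compared libraries (0.0676 and 0.0717) and with a robust dispersion prior (0.0551 and 0.0755). Among lists camera did not call, amino acids had 2 higher and 3 lower of 24 (gatm -2.40 ± 0.40; pck2 -0.94 ± 0.11; fbp1b -5.19 ± 0.74), endocrine pancreas 0 and 3 of 12 (isl1 -0.40 ± 0.08; pax6b -0.41 ± 0.07) and pronephros 4 and 1 of 20. The pronephros gene hnf1ba rose by 0.52 ± 0.12 (adjusted p = 0.0118), a call lost without sibling replicate 1 (adjusted p = 0.0536). In exocrine pancreas 1 of 7 fell, cpa1 (-3.04 ± 0.77, adjusted p = 0.0181), which had 6 counts in the knockouts and lost its call without sibling replicate 4 (adjusted p = 0.0595) or knockout replicate 3 (adjusted p = 0.0507), and in limma-voom (0.0605). None of 25 replication and 23 erythroid genes was called. The median of exocrine pancreas was 0.05 while the test pointed lower, that of replication -0.02 while it pointed higher, and the erythroid mean was near 0 with the test higher. The higher and lower members adjusted over the list alone were 48 and 2 (ribosomal), 6 and 0 (p53), 9 and 0 (lysosome), 5 and 1 (endothelium), 8 and 2 (growth factors) and 4 and 0 (leukocytes). In the other lists they were 3 and 4 (amino acids), 0 and 3 (endocrine), 4 and 1 (pronephros), 1 and 2 (exocrine) and 0 in the last pair.

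Over all genes 1146 were higher and 1271 lower at 48 hpf, 286 and 475 of them by more than 2-fold. The largest rises were arf4b (6.16 ± 0.53), hpxa (5.86 ± 1.18), gtf3ab (5.66 ± 0.55), tcap (5.24 ± 0.81), igfbp1b, klf10 (4.22 ± 0.83), scd (4.17 ± 0.31) and cbx7a. Without knockout replicate 1 the rise of cbx7a (4.08 ± 1.09, adjusted p = 0.0242) was 2.13 (adjusted p = 0.153) and that of tcap 4.14. The cbx7a call was also lost without any 1 of the 4 sibling libraries. Without knockout replicate 2 hpxa was at 5.09. In limma-voom the calls of hpxa (adjusted p = 0.0780), klf10 (0.144), cbx7a (0.249) and ces3 (0.137) were lost, and that of cbx7a also with a robust dispersion prior (0.0640). The largest falls were itih3a, with 0 counts in the knockouts and at least 1494-fold lower, the apolipoproteins above, cyp4v8, akr1a1a and the carboxylesterase genes ces3 (-9.48 ± 1.18, with all knockout counts in replicate 1) and ces2 (-8.92 ± 1.25). With 2 knockout counts each, cyp4v8 was lower by a ratio of 986 (95% counting interval 272 to 8144) and akr1a1a by a ratio of 835 (231 to 6904). These counts came from knockout replicates 4 and 1 alone, so without them only a lower bound of the fall is left. The higher genes numbered 706, 680 and 721 without sibling replicates 1, 2 or 3, and the lower genes 826 and 829 without sibling replicates 2 or 3. With upper quartile scaling 1309 genes were higher and 1160 lower, which turned the balance.

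**Figure D2:**
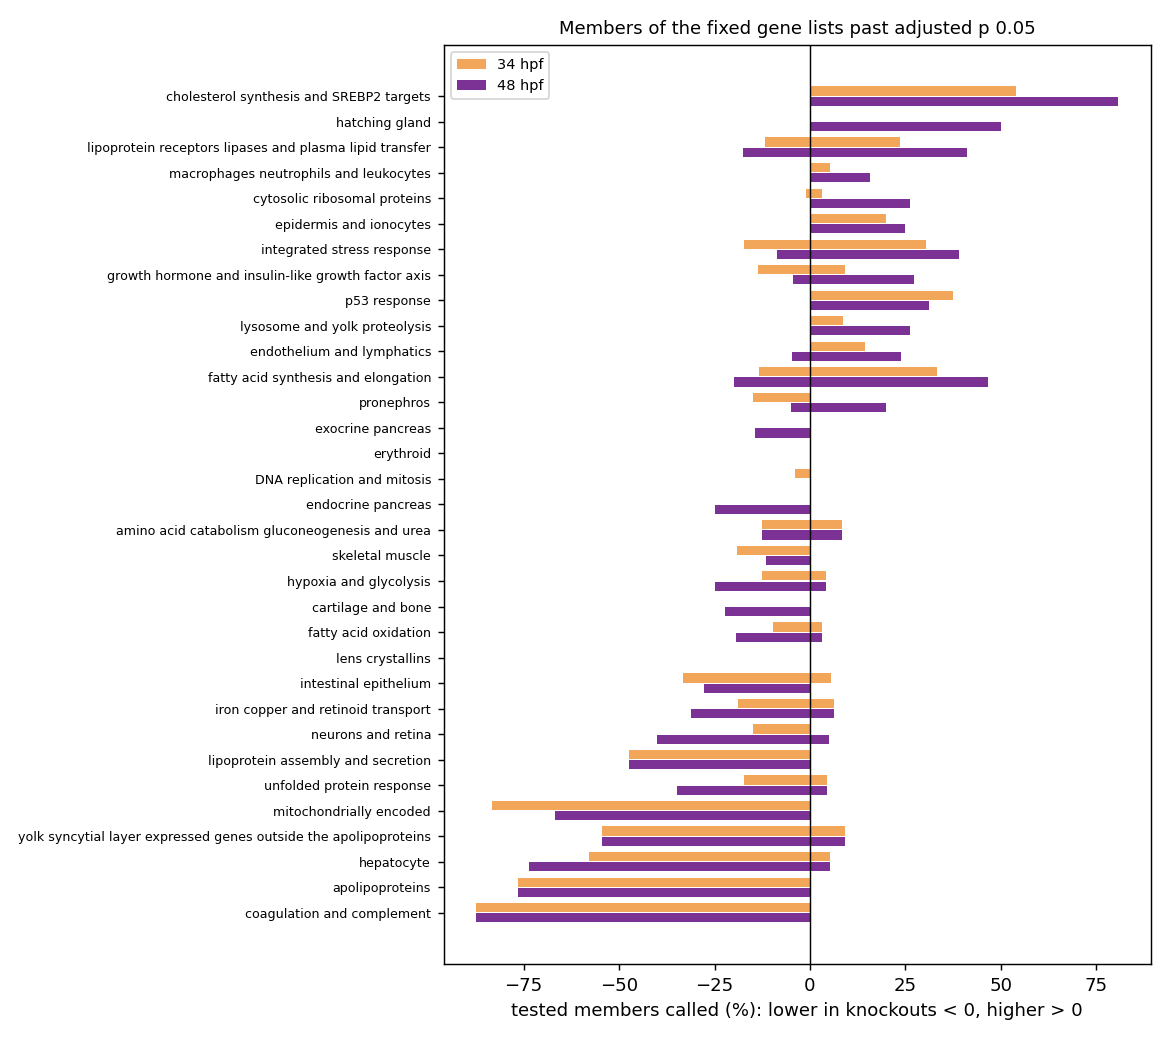
Share of the tested members (%) of each of the 33 fixed gene lists that were lower (bars to the left, below 0) or higher (bars to the right) in knockouts at 34 hpf (orange) and 48 hpf (purple), ordered by the list's median log2 fold change at 48 hpf. Coagulation and complement (21 of 24 lower at both stages) and cholesterol synthesis (14 and 21 of 26 higher) mark the ends.

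The knockout effects of the stages were then set side by side; these comparisons share no library. Genes such as apoea, itih3a, fabp2 and c8b were lower and scd, igfbp1b, pltp and ddit3 higher at both stages. In all, 452 genes were higher at both (46.9 from independent lists), 625 lower at both (66.2) and 9 moved in opposite directions (112). Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.656 and Spearman's rho = 0.509. Pearson's r was 0.258 with no filter on low counts and 0.304 with DESeq2, which was also run without that filter. At 34 hpf alone 1154 genes were called and at 48 hpf alone 1331, and of these 36 passed the test of the difference itself.

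**Figure D3:**
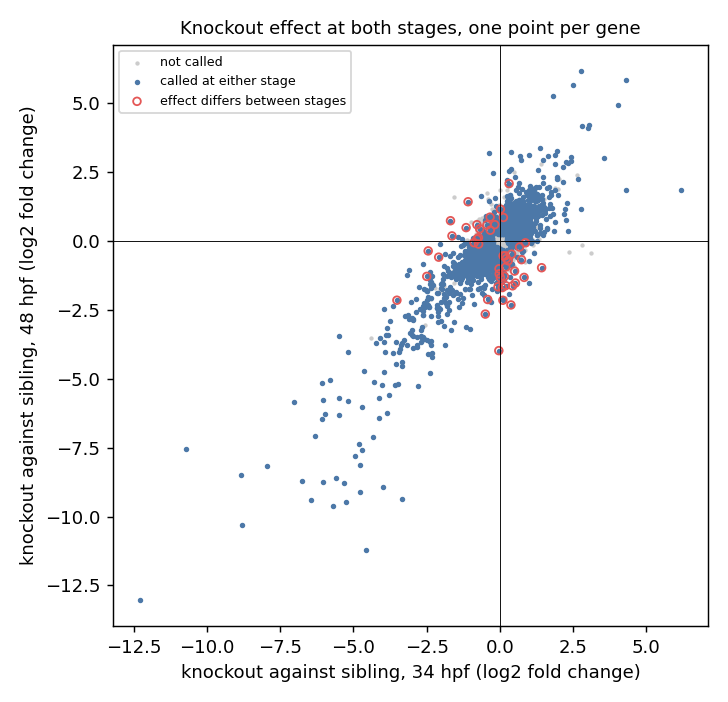
Log2 fold change of knockouts against siblings at 34 hpf (horizontal) and 48 hpf (vertical) for the 17681 genes with an average log2 CPM of at least 1. Grey points were called at neither stage, blue points at either, and red circles mark genes whose effect differed between the stages.

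The test of the difference asked which knockout effects changed from 34 to 48 hpf. The retinal neuron factor gene atoh7 was lower in knockouts at 34 hpf (-1.68 ± 0.21) and higher at 48 hpf (0.73 ± 0.20), a difference of 2.42 ± 0.29 (adjusted p = 0.000918). The glycogen phosphorylase gene pygl changed by -0.50 ± 0.15 and then by -2.65 ± 0.15 (difference -2.16 ± 0.21, adjusted p = 0.000208). The difference was also below 0 for gnb3a, of cone phototransduction (-3.94 ± 0.58, or -3.34 without knockout 34 hpf replicate 2), ccdc88aa (-2.70 ± 0.36), syt5b (-2.40 ± 0.26) and bhlhe23 (-2.26 ± 0.32). At 34 hpf gnb3a, ccdc88aa and bhlhe23 reached at most 1.03 CPM in any library, so little effect could be seen there. At 48 hpf gnb3a stood at 26.1 to 42.1 CPM in siblings and 0.943 to 2.80 in knockouts. Knockouts were higher for syt5b at 34 hpf (3.58 to 4.38 CPM, siblings 1.09 to 2.16) and lower at 48 hpf. In other genes the difference went the other way. Those of ddhd2 (2.08 ± 0.26), tnfrsf9a (1.76 ± 0.27) and the kidney cadherin gene cdh17 (0.82 ± 0.12) were higher. The protease genes ctss2.1 (2.51 ± 0.47, adjusted p = 0.0321) and ctsh (1.82 ± 0.35, adjusted p = 0.0456) lost their calls in 10 and 12 of 16 omissions of a library (highest adjusted p = 0.104 and 0.124), and ctss2.1 also with the replicate block (adjusted p = 0.0719). Both were lost with a robust dispersion prior (0.0876 and 0.0643) and in limma-voom (0.138 and 0.0660), which also ended the calls of gnb3a (0.134) and tnfrsf9a (0.0610). That of prox1a (-0.72 ± 0.13, adjusted p = 0.0228) was lost without sibling replicate 3 at 34 hpf, sibling replicates 2 or 3 at 48 hpf, or knockout replicates 3 or 4 at 48 hpf (highest adjusted p = 0.0721).

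In total 21 genes had a higher and 28 a lower log2 fold change at 48 than at 34 hpf. The higher count was 13 without sibling replicate 3 at 34 hpf, sibling replicate 3 or knockout replicate 3 at 48 hpf, and 62 without knockout replicate 4 at 34 hpf. The lower count was 51 without that last library, 18 and 16 without sibling replicate 3 or knockout replicate 3 at 34 hpf, 17, 10 and 11 without sibling replicates 1, 2 or 3 at 48 hpf, and 11 and 16 without knockout replicates 3 or 4 at 48 hpf. Camera called 8 lists higher, led by cholesterol synthesis (adjusted p = 0.367 with an estimated correlation) and the stress response (adjusted p = 0.367 with an estimated correlation). It called 6 lower, led by neurons and retina (adjusted p = 0.367 with an estimated correlation), cartilage (adjusted p = 0.367 with an estimated correlation) and apolipoproteins (adjusted p = 0.573 with an estimated correlation). None of the 14 kept its call. In these 5 lists 1 member passed, atoh7 in neurons and retina, and it moved higher, against the direction of its list. Adjusted over the list alone, 5 stress response genes were higher and 1 lower, 5 neuronal genes and 4 cartilage genes were lower and 1 neuronal gene higher. With the replicate block the erythroid list was also called higher (adjusted p = 0.0130), with 0 of 23 members called and, without the block, adjusted p = 0.878 with an estimated correlation.

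The last comparison described the siblings from 34 to 48 hpf, where the stage is also the batch label and cannot be told apart from it. The largest rises were those of col10a1a, a collagen gene of cartilage and bone (8.15 ± 0.39), the lens crystallin genes crygm2d11 (6.58 ± 0.60, or 7.49 without sibling 34 hpf replicate 4) and crygm5 (5.03 ± 0.42), gnb3a (6.71 ± 0.39), the muscle gene ampd1 (5.72 ± 0.38) and igfn1.3 (6.79 ± 0.91). The protease genes ctslb (-6.33 ± 0.51), ctss2.1 (-4.46 ± 0.37) and ctsll (-3.37 ± 0.56), acp5a (-4.19 ± 0.48), prtgb (-4.08 ± 0.33) and the troponin gene tnni2b.1 (-3.84 ± 0.31) fell. In neurons and retina 17 of 20 rose and 1 fell, and in the hatching gland list 7 of 10 fell, both held by camera (adjusted p = 0.0311 with an estimated correlation for each). In lens 17 of 20 rose (adjusted p = 0.197 with an estimated correlation) and in replication and mitosis 23 of 25 fell (adjusted p = 0.197 with an estimated correlation). In cartilage 11 of 18 rose and 1 fell (adjusted p = 0.216 with an estimated correlation) and in endocrine pancreas 4 of 12 rose (adjusted p = 0.197 with an estimated correlation). Among ribosomal proteins 51 of 95 fell and 6 rose (adjusted p = 0.973 with an estimated correlation). Adjusted over the list alone, the higher and lower members were 17 and 1, 0 and 7, 17 and 0, 0 and 24, 11 and 2, 5 and 0, and 6 and 57. The value of hnf4b was -0.70 (adjusted p = 0.283), or -0.08 without sibling 34 hpf replicate 1. Over all genes 4400 were higher and 3771 lower at 48 hpf.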

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

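The tests of stage position, of genes near the targeted loci and of a lower cell yield were chosen after the results were seen.

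In 363 groups of 4 libraries (a named gene or measure in a group), 34 held a library far from the other 3 by Dixon's criterion (9.37%). For independent normal values chance marks about 1 in 20, or 18.2. The CPM of named genes are neither, so this rate is a rough guide. Groups with counts in 1 library only were marked by construction, as for f7, cyp4v8, ces3 and akr1a1a in knockouts. Of the 34 marks 9 stood in knockout 48 hpf replicate 1 and 7 in knockout 34 hpf replicate 4. In knockout 48 hpf replicate 1 the CPM were 23.5 for il1b, 175 for mmp9, 95.4 for mmp13a, 34.7 for ctslb, 63.0 for tcap, 69.8 for cbx7a, 106 for lpl, 0.0929 for ces3 and 0.0464 for akr1a1a. In knockout 34 hpf replicate 4 they were 10.7 for mttp, 68.5 for lipg, 33.4 for fga, 4.70 for fgb, 3.75 for rbp2a and 26.8 for fbp1b, and its stage position was -0.0148. A gene was checked only in the groups of the comparison it was named for. Genes named at 48 hpf alone, picked after their values were seen, also stood apart there. This library held 149 CPM of apoa4b.1, 50.6 of apoc2, 63.1 of ces2 and 179 of pla2g12b. The highest values in the other knockouts at 34 hpf were 0.341, 0.994, 2.66 and 29.3.

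Knockout 34 hpf replicate 2 stood apart for hpxa (61.0 CPM), f7 (0.170), fabp2 (6.87), gnb3a (0.625) and otx5 (1.76), and replicate 3 for soat1 (1.88). At 48 hpf matn1 stood apart in knockout replicate 2 (0.719), fga (20.8) and cpa1 (0 CPM) in replicate 3 and cyp4v8 (0.0468) in replicate 4. Sibling libraries stood apart at 34 hpf for itih3a in replicate 2 (27.8), cdh17 (113) and prox1a (37.7) in replicate 3 and syt5b in replicate 4 (2.16), and at 48 hpf for ctsba (139) and col10a1a (34.0) in replicate 1, prox1a in replicate 2 (100.6) and isl1 in replicate 4 (55.3).

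By the test of the difference, the knockout effect at 48 hpf lay above that at 34 hpf on the log2 scale for atoh7 (2.42), ctss2.1 (2.51), ddhd2 (2.08), ctsh (1.82), tnfrsf9a (1.76) and cdh17 (0.82). It lay below it for gnb3a (-3.94), ccdc88aa (-2.70), syt5b (-2.40), bhlhe23 (-2.26), pygl (-2.16) and prox1a (-0.72).

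Genes of the yolk syncytial layer, liver and plasma fell in the knockouts: of 63 members of 4 lists, 46 fell at 48 hpf, 2 rose and 15 were not called. Scaling between libraries is argued against, since the apolipoprotein median at 48 hpf stayed at -3.55 or lower under 3 scalings. A lower yield of these cells may account for part of the falls and cannot be told apart from lower expression per cell in whole embryos. The 2 members that rose and the spread of the falls beyond their standard errors (heterogeneity statistic 803) do not exclude it, because other tissues express some of these genes. An effect of the genotype on transcription stays open as well.

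On an axis from the sibling mean at 34 hpf (0) to that at 48 hpf (1), built from siblings of the other replicate numbers, knockouts at 48 hpf lay at 0.774 ± 0.0831 and siblings at 0.954 ± 0.0522 (SD, n = 4), a difference of -0.180 (exact permutation p = 0.0286, two-sided, the smallest possible; 0.125 within the numbered pairs, also the smallest possible). All 4 numbered pairs differed the same way, by -3.44 SD of the paired differences, which argues against clutch differences shared within a number as far as the numbers pair the samples. At 34 hpf the difference was 0.0150 (exact permutation p = 0.571), so a shift of like size along this axis at that age is argued against. The axis holds only changes between 34 and 48 hpf, so it need not show a delay in earlier or passing changes. Delayed development of the knockouts may account for the shift at 48 hpf, and sampling at an earlier age would give the same values. A slower change of a subset of tissues stays open.

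Variants linked to the targeted alleles could raise calls near these loci. Among the 100 nearest tested genes of hnf4a 18 were called at 48 hpf, and 6.53% of windows held at least as many. At 34 hpf 14 were called (17.6% of windows). For hnf4b 13 were called at 34 hpf (25.6%) and 14 at 48 hpf (26.2%). Only 79.0% of tested genes had a position, under the 80% set for the check, so the check is void.

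The real split gave the most calls at 34 hpf (2240, highest of the other 34 splits 25) and at 48 hpf (2417, highest other 2). It also did so for the difference (49, highest of the other drawn splits 7) and for the stages (8171, highest other 3). In each, 1 split, the real one, gave as many calls, which argues against chance if the samples can be exchanged freely. The spread was estimated anew in each split, and mixed groups widen it where genotypes or stages differ. Few calls in the other splits were therefore likely from the start. If the numbers pair the samples, the comparable splits are those that part as many pairs. The other splits that part all 4 pairs gave at most 0 calls at both stages. Only 8 splits at each stage part all pairs, the real one included, too few to exclude chance if the samples are paired. The split with 25 calls parts replicates 1 and 2 from 3 and 4 at 34 hpf, the structure of the component described above, and the blocked counts there were 1014 higher and 1419 lower.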

How the results depend on the processing

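The tests of the ribosomal list without S6 kinases and of the stage position within numbered pairs were chosen after the data were seen. Without the kinases 2 of 84 members rose at 34 hpf and 25 at 48 hpf. Of 1168 values of the 65 named genes at 34 hpf under the alternatives, 1119 kept their side of the threshold and 49 lost the call. Of 1321 for 74 genes at 48 hpf, 1265 and 56 did so, and of 374 for 15 genes of the difference, 335 and 39. All 269 of the 15 stage genes kept theirs. No gene with a call reversed, while uncalled genes near 0, such as hnf4a, changed sign (0.10 at 34 hpf without knockout replicate 4). Named genes that lost a call in at least 1 alternative numbered 24, 25, 6 and 0. Most named genes were chosen for a large change or a small p, so these shares do not stand for all calls. Of all main calls at 34 hpf, 52.7% were kept with only the compared libraries and 60.6 to 89.1% when a library was left out. Leaving out a library kept 61.0 to 82.3% at 48 hpf and 49.0 to 100% for the difference. Depth limits genes with few counts, and 0 of the simulated 1.5-fold changes were found in the test of the difference of the knockout effect.

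Against a fold of 1.5 the higher and lower counts were 64 and 229 at 34 hpf, 118 and 287 at 48 hpf, 3 and 7 for the difference and 1900 and 574 for the stages, and 32 and 167 genes were higher and lower at both stages; the test asks for a larger change. With only the compared libraries 491 and 739 genes were called at 34 hpf, and 301 were higher at both stages. The same choice gave 1362 and 1639 at 48 hpf and 5307 and 4564 for the stages. The main fit shares 1 estimate of the spread over all groups. Pairs of knockout libraries at 34 hpf had mean ratios to counting noise of 30.4 to 134, and pairs in the other groups 8.29 to 55.8. The pairs with knockout 34 hpf replicate 4 had the ratios of 77.7 to 134. Without that library the calls at 34 hpf rose from 985 higher and 1255 lower to 1226 and 1982. The fit with only the compared libraries estimates the spread anew but also changes the filter and the scaling. It therefore does not show how much the shared spread alone moved the calls. For the difference DESeq2 called 79 and 99 genes and limma-voom 18 lower, and the cause was not tested. The correlation of the effects was 0.809 at an average log2 CPM of at least 1 and 0.769 with a CPM of at least 1 in 4 libraries. It was 0.258 with no filter and 0.304 with DESeq2. The filters change which low genes enter, and DESeq2 was also run without a filter on low counts. Its 0.304 therefore includes low genes, and its correlation over the filtered genes was not computed.

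Leaving out each library gave 522 to 1226 higher and 864 to 1982 lower genes at 34 hpf, 680 to 1093 and 826 to 1258 at 48 hpf, and 13 to 62 and 10 to 51 for the difference. With an estimated correlation 0 lists were higher at 34 hpf, 6 higher and 7 lower at 48 hpf, 0 and 0 for the difference and 1 and 1 for the stages. By fry, directional, 0 and 0 lists passed for the difference and 9 were higher for the stages. The correlation of the knockout effect at 34 hpf with the stage effect (-0.108) turned to 0.0483 and 0.0299 when siblings 1 and 3 or 1 and 4 served the knockout effect; the cause was not tested.

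With the replicate block 1014 and 1419 genes were called at 34 hpf, 1165 and 1386 at 48 hpf and 24 and 29 for the difference. The block ended the calls of il1b, mmp9, mmp13a and ctss2.1 and added the 6 list calls given with the comparisons; it changed no other call of a named gene or list. List medians changed sign between scalings for skeletal muscle at 34 hpf and for replication and the erythroid list at 48 hpf, all near 0. Alignment, counting and annotation were not repeated, and neither were other gene models or fits with further covariates.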

Other observations

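All tests in this part were set before their results were seen; the family members named were chosen after their values were seen.

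Outside the fixed lists, genes were grouped by the letters of their symbol into 627 families of at least 5 tested genes and tested for calls with Fisher's exact test, adjusted over 2508 tests. In the her family, transcription factors of the Notch pathway, 7 of 15 members rose at 48 hpf (adjusted p = 0.00799), such as her2 (0.81 ± 0.19), her4.4 (0.66 ± 0.12) and her8a (0.56 ± 0.12); the her4 copies are uncertain. Of 5 arrestin domain genes 4 rose at both stages (adjusted p = 0.0238 for each), with arrdc2 at 1.21 ± 0.22 and 1.73 ± 0.22. Of 360 solute carrier genes 39 fell at 48 hpf (adjusted p = 0.0315), among them the glucose transporter gene slc2a2 (-5.11 ± 0.72), slc13a2 (-3.52 ± 0.32) and slc17a5 (-1.66 ± 0.13).

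Across genes, the knockout effect at 48 hpf ran against the sibling stage effect. With sibling replicates 1 and 2 used for the first and 3 and 4 for the second, the correlation was -0.215. It lay below all 20 simulated unchanged groups (-0.0167 to 0.0269), and the other halvings gave -0.217 to -0.129. With all siblings in both, the correlation was -0.300 against a simulated -0.210 to -0.188, with a covariance of -0.144 against -0.0535. The simulation drew each library independently, without the structure that replicates share in both genotypes. Its ranges, here and below, are therefore likely too narrow for these data. Knockouts at 48 hpf may therefore resemble the earlier stage over many genes, a hypothesis that sampling age leaves open. At 34 hpf the correlation was -0.108 in the first halving (simulated -0.0216 to 0.00606), positive in 2 of the 5 others and negative in 3 (-0.0506 to 0.0483). With all siblings in both it was 0.0884 against a simulated 0.184 to 0.214.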
